A study of Homo sapiens with 4 samples.

How the data were processed

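The samples were 4 libraries from HEK-293 Flp-In T-REx cells carrying FLAG-PTBP1, 2 of eCLIP and 2 of size-matched input, grouped by their titles. Per the labels' protocols, the transgene was induced with doxycycline at 1 µg/mL for 48 to 72 h, cells were crosslinked with ultraviolet light at 400 mJ per square cm, and both kinds of library were made with the eCLIP procedure. Nothing in the labels says that the replicates came from separate cultures, so differences between replicates may be technical. Per the submitters' processing notes, cutadapt and STAR were used and the build was hg19. The cluster caller, its settings, the gene annotation and any removal of duplicate reads are not given in the sources used here. Each deposited list belongs to 1 library, so clusters were called per library and not on pooled replicates.

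Each deposited cluster was read as having a position, strand and summit, a name, a score and a p-value. This layout, the summit and p-value included, was inferred from the values and not from a header. The deposited p-value of a cluster never exceeded 0.05. The deposited score equalled minus 10 times the log10 of that p-value, rounded down and limited to 1000, and was 0 where the p-value was given as 0. The deposited name holds an Ensembl gene ID, the number of the cluster within the gene, and a last whole number of at least 3, which was taken as the number of reads in the cluster; this reading comes from the values and not from a header. Read numbers and p-values are the authors' and were used to describe, rank and filter clusters. Reads outside clusters were not analysed here, so the totals given are of cluster reads and not of whole libraries. A place with no cluster may still hold reads, most of all in input 2, whose list is 67.0 times smaller in reads than that of input 1.

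Clusters were compared by overlap on the same strand of at least 1 bp, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9. For a chance value, each cluster was moved to a random place within the span of its gene, from the first to the last cluster of that gene in any of the 4 lists, 100 times with a fixed seed. This keeps the gene, and so its expression, but not the exon structure. The p-value is the share of moves with as large an overlap, counting the real one. The procedure was tested on simulated data of 20000 clusters over 21464 gene spans for the comparison of eCLIP 2 with eCLIP 1: with 20.1% of clusters planted on eCLIP 1 clusters it returned 20.2%, with 59.7% planted it returned 59.6%, and with none it returned 0.0734% (permutation p = 0.337). The returned value is the overlap above the moved mean, as a share of what that mean leaves, and is not used in the results. The simulated background was placed by the same random moves. The simulation therefore checks the calculation and cannot show that the moves suit real clusters. An eCLIP-only shared cluster is an eCLIP 2 cluster that touches eCLIP 1 and neither input. Shares per library were compared between the groups by an exact permutation of the 4 libraries, two-sided, which cannot go below 0.33. Wilson intervals at 95% cover counting error only, and clusters within a gene are not independent.

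The clusters carry Ensembl IDs, and 0 of them could be paired with a symbol by the tables used here, so no gene is named. Of the analyses set out before the data were examined, those of the 12 fixed gene lists, the gene encoding PTBP1, transcript regions, CU-rich motifs, stop codons, annotated 3′ ends and splice sites need gene names or an hg19 sequence and annotation, and were not run here. The ranking of leading genes followed the rule set beforehand for the case without regions: the 20 genes with the best eCLIP-only shared cluster by the larger of both replicates' p-values, ties by reads, and the 5 genes with the most input-only shared clusters. IDs are printed for the first 2 of the eCLIP ranking and, since its first gene led the input ranking too, for the next 2 of the input ranking; other loci are given by position. The genes richest in number, the mitochondrial share, neighbouring clusters, span position, summits and profiles were added after the data were seen. Alternatives were stricter p-values (1e-05 and 1e-10), lists of equal length, coverage of at least 50% of the cluster, each replicate left out, each eCLIP library set only against the input of its number, and clusters with an input at least 4 times lower.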

Results

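FLAG-tagged PTBP1 was crosslinked to RNA in HEK-293 Flp-In T-REx cells, a human embryonic kidney line in which an integrated transgene is switched on by doxycycline. PTBP1, the polypyrimidine tract-binding protein, is a nuclear and cytoplasmic RNA-binding protein that recognises CU-rich RNA. Enhanced crosslinking and immunoprecipitation (eCLIP) sequences the RNA fragments that remain bound to the precipitated protein, and a size-matched input library samples the RNA of the same gel range without the immunoprecipitation. The series held 2 eCLIP libraries and 2 size-matched inputs, numbered 1 and 2 in each group, and each library came with its own list of read clusters in hg19 coordinates. The lists differed widely in length and depth. The eCLIP replicate 1 list held 550105 clusters with 4523346 cluster reads and covered 19.1 Mb, and the eCLIP replicate 2 list held 85812 clusters with 444908 reads and covered 2.61 Mb. The input replicate 1 list held 379404 clusters with 2743532 reads over 13.2 Mb, and the input replicate 2 list held 4808 clusters with 40945 reads over 0.0972 Mb. No cluster held fewer than 3 reads, and the median cluster held 5, 4, 4 and 4 reads in the same order.

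The first comparison asked whether PTBP1 eCLIP clusters recurred at the same RNA positions and whether these differed from the positions of input clusters. Of the 85812 eCLIP 2 clusters, 65.8% (95% Wilson interval 65.5 to 66.1) touched an eCLIP 1 cluster on the same strand, and 22.9% (22.6 to 23.2) touched an input 1 cluster. When each eCLIP 2 cluster was moved at random within its own gene, 7.58% ± 0.0770 (SD over 100 moves) touched eCLIP 1 and 5.96% ± 0.0774 touched input 1. The observed overlap was 8.67 times the within-gene value for eCLIP 1 and 3.85 times for input 1, and both exceeded all 100 moves (permutation p = 0.0099, one-sided, the smallest that 100 moves can give). All 12 ordered pairs of libraries gave this p, which Benjamini-Hochberg adjustment left at 0.0099. The moves keep the gene but not its exons, and the chance value does not allow for exon structure. The inputs also recurred at common positions: 73.9% (72.6 to 75.1) of the 4808 input 2 clusters touched input 1, against 20.9% (19.8 to 22.1) that touched eCLIP 1 and 12.2% (11.3 to 13.2) that touched eCLIP 2. With the 4808 most significant clusters of every library, 50.3% of eCLIP 2 clusters touched eCLIP 1 and 12.4% touched input 1. At that length 15.2% of input 2 clusters touched input 1, 3.56% touched eCLIP 1 and 4.58% touched eCLIP 2, so that the recurrence of input clusters depended strongly on the length of the input 1 list.

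The excess of eCLIP 1 over input 1 was present on every nuclear chromosome with at least 100 eCLIP 2 clusters. On these 23 chromosomes the share that touched eCLIP 1 ranged from 62.8% to 69.3%, and the share that touched input 1 from 18.9% on chromosome 2 to 30.0% on chromosome 19. The 83 eCLIP 2 clusters on the mitochondrial genome differed from the nuclear ones, since 98.8% touched eCLIP 1 and 90.4% touched input 1. That genome held 135 eCLIP 1 and 155 input 1 clusters. No value after random moves was computed for it alone, so the density of clusters there may account for this. Clusters on the opposite strand rarely met: 0.0140% of eCLIP 2 clusters lay opposite an eCLIP 1 cluster. Among the 56444 shared eCLIP clusters, the summits of both replicates lay a median of 7 nt apart, and 65.0% lay within 10 nt. Close summits are largely built in here, since these clusters were picked for touching. Over the whole lists the median cluster width was 30 nt in eCLIP 1 and 27 nt in eCLIP 2. No chance value was computed for summit distances. Of the 16386 eCLIP 2 clusters that touched both eCLIP 1 and input 1, 55.3% had their summit closer to that of eCLIP 1 and 37.6% closer to that of input 1, with median distances of 6 and 9 nt. Input 1 clusters were wider, with a median of 33 nt, so this contrast cannot be told apart from cluster width.

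**Figure D1:**
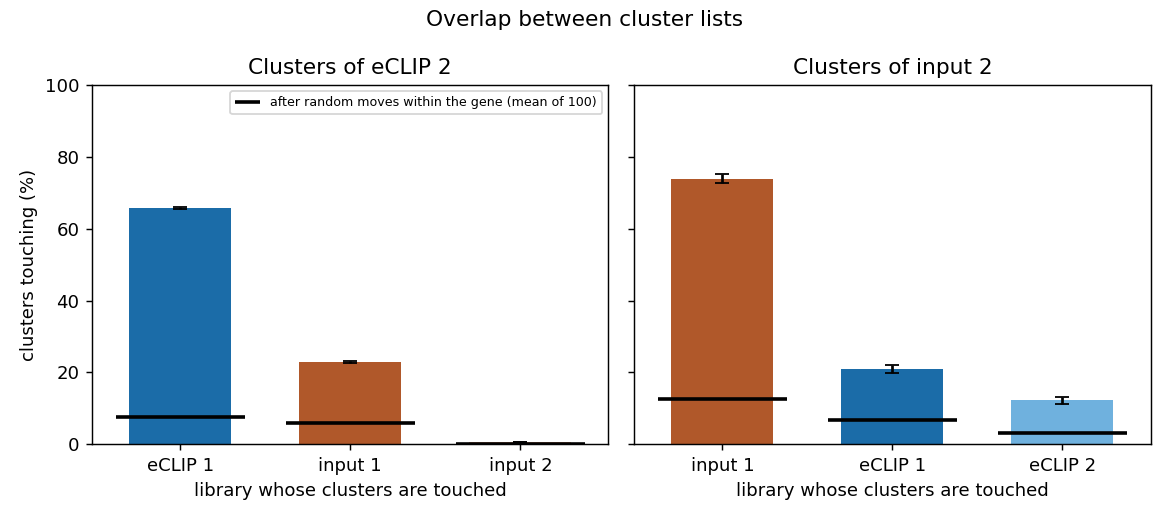
Percent of clusters (y axis) of eCLIP 2 (left) and input 2 (right) that touched a cluster of each other library (x axis) on the same strand by at least 1 bp; error bars are 95% Wilson intervals and black lines are the means after 100 random moves within the gene. The highest bar in each panel is the other replicate of the same group, 65.8% for eCLIP and 73.9% for input.

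Overlap depended on the number of reads in the eCLIP 2 cluster. Of the 40159 clusters with 3 reads, 49.9% touched eCLIP 1 and 14.2% touched input 1. The 22589 clusters with 5 to 9 reads touched eCLIP 1 in 85.0% and input 1 in 31.7% of cases. The 978 clusters with 20 or more reads touched eCLIP 1 in 99.2% and input 1 in 76.0%, so that the strongest clusters were also those most often called in the input. The share that touched eCLIP 1 and neither input was 40.5% at 3 reads, 55.8% at 5 to 9 reads and 23.2% at 20 or more reads.

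**Figure D2:**
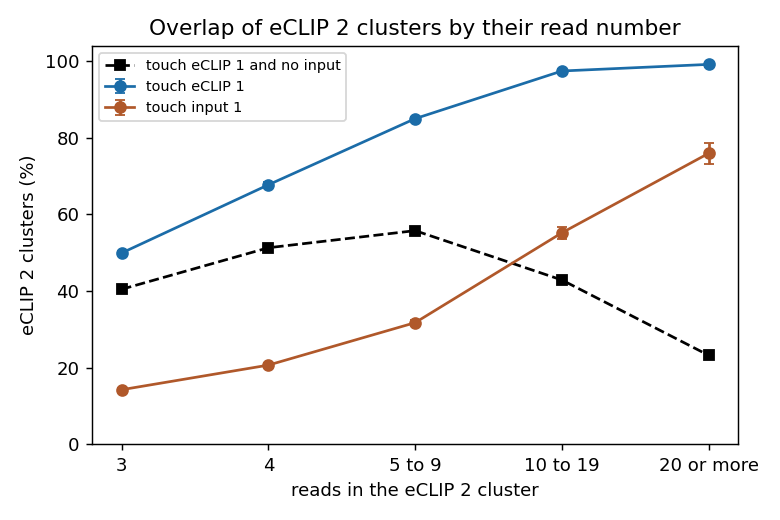
Percent of eCLIP 2 clusters (y axis) that touched eCLIP 1, touched input 1, or touched eCLIP 1 and no input, by the number of reads in the eCLIP 2 cluster (x axis); error bars are 95% Wilson intervals. Contact with eCLIP 1 goes from 49.9% to 99.2% and contact with input 1 from 14.2% to 76.0%, whereas the eCLIP-only share is highest, 55.8%, at 5 to 9 reads.

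The second comparison took the clusters found in both eCLIP replicates and in neither input, called eCLIP-only shared clusters here. There were 40044 of them, 70.9% (70.6 to 71.3) of the shared eCLIP clusters, in 7342 genes as the authors assigned them. They were spread over many genes: 2466 genes held 1, 1057 held 10 or more, and the 100 richest genes held 15.8% of all. Of the 7342 genes, 7184 also had a cluster elsewhere in input 1. The count is a comparison of lists with no p-value over libraries, and it rests on input 1, since only 14 shared clusters touched input 2 but not input 1. With clusters of p-values below 1e-05 alone in all 4 lists, the count was 5384 in 2211 genes.

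The gene with the most significant eCLIP-only shared cluster was ENSG00000229807, on the minus strand of chromosome X. Its best cluster, at chrX 73047686 to 73047728, held 1718 reads in the overlapping eCLIP 1 cluster and 845 reads in eCLIP 2. The gene carried 2.89% and 6.33% of all cluster reads in eCLIP 1 and 2, and 4.15% and 1.58% in input 1 and 2, so its total did not separate the groups. Along the gene, its reads were compared in 1 kb bins; the gene was picked for a cluster absent from both inputs, so a higher eCLIP share in the bin that holds that cluster is partly built in. That bin, from 73047001 to 73048000, held 28.4% of the gene's cluster reads in eCLIP 1 and 39.2% in eCLIP 2, against 4.96% in input 1 and 11.0% in input 2. Over the other 32 bins of the gene, rescaled to 100% without that bin, the profiles of both eCLIP libraries had 87.7% of their area in common and those of both inputs 73.6%, while the 4 eCLIP and input pairs had 55.6% to 69.7%.

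**Figure D3:**
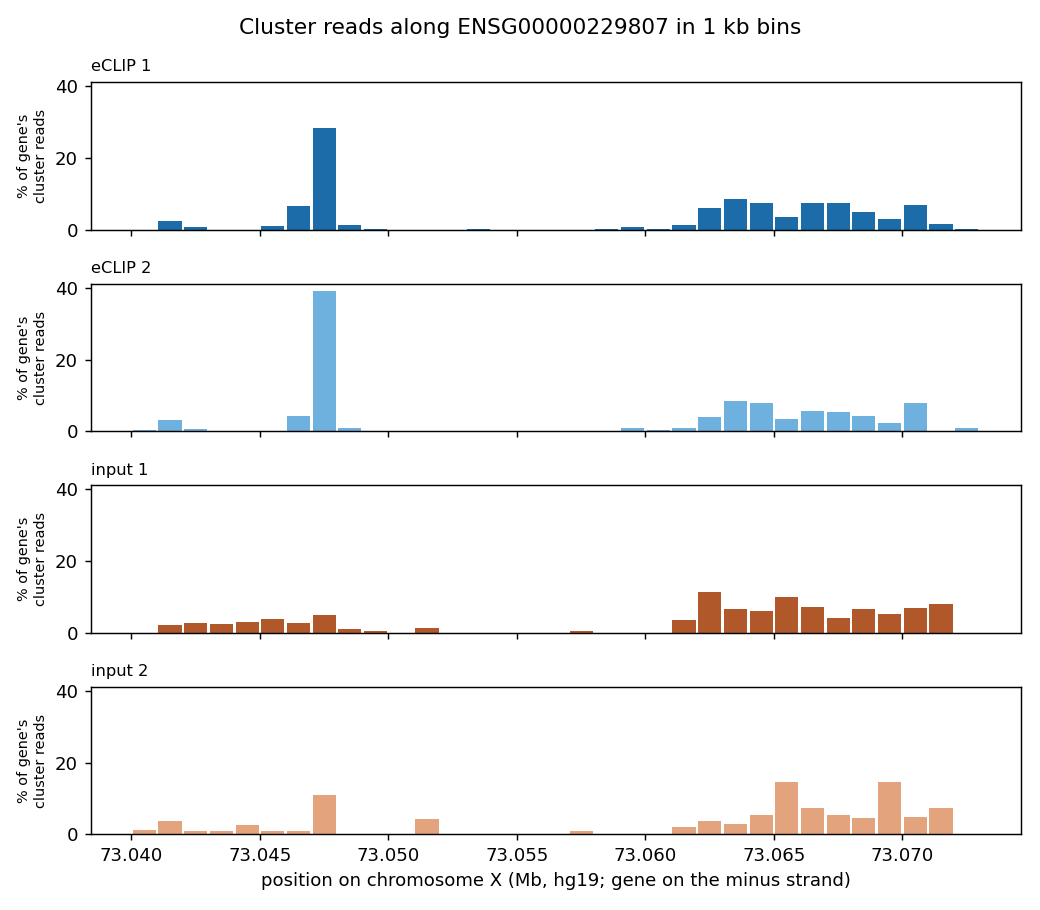
Percent of the cluster reads of ENSG00000229807 (y axis) in 1 kb bins along chromosome X (x axis, Mb, hg19), 1 panel per library. The bin at 73047001 to 73048000 holds 28.4% and 39.2% of the reads in the eCLIP libraries and 4.96% and 11.0% in the inputs.

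The second-ranked gene, ENSG00000028310 on the minus strand of chromosome 5, had its best cluster at 852877 to 853098 with 118 reads in eCLIP 2, and the overlapping eCLIP 1 cluster held 287 reads. It held 13 eCLIP-only shared clusters. Its share of all cluster reads was 0.187% in eCLIP 1 and 0.238% in eCLIP 2, against 0.0295% in input 1, and it had no cluster in input 2. The next loci by the same ranking were on the minus strand of chromosome 6 (99962868 to 99962893, 56 reads in eCLIP 1 and 40 in eCLIP 2), the minus strand of chromosome 11 (10823118 to 10823160, 132 and 45 reads), and the plus strand of chromosome 1 (2187674 to 2187793, 143 and 52 reads). They were followed by the minus strand of chromosome X (73491711 to 73491757, 149 and 40 reads), the plus strand of chromosome 19 (56173564 to 56173659, 186 and 54 reads) and the plus strand of chromosome 11 (65199696 to 65199758, 203 and 81 reads). Coordinates are those of the eCLIP 2 cluster. Among the 20 best-ranked genes, 9 had a lower share of cluster reads in eCLIP 1 than in input 1, and 0 had a lower share in eCLIP 2 than in input 2, where 11 had no cluster. The gene at rank 9, with its cluster at chromosome 1, 8930993 to 8931056, carried 0.0128% of eCLIP 1 and 0.0707% of input 1 cluster reads, and the gene at rank 11, at chromosome 11, 65271649 to 65271700, carried 0.170% and 0.574%; in pair 2 the shares were 0.0166% against no cluster for the former and 0.257% against 0.147% for the latter.

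Ranked by number, the genes richest in eCLIP-only shared clusters had long spans, a span being the stretch from the first to the last cluster of a gene in any library. The richest, on the plus strand of chromosome 7 (69063915 to 70255745), held 170, with 1635 clusters in eCLIP 1, 359 in eCLIP 2 and 1059 in input 1. It was followed by genes on chromosome 10 (52751205 to 54044913, 163 of 318 eCLIP 2 clusters), chromosome 16 (78133622 to 79245974, 155 of 354) and chromosome 22 (28374246 to 29075681, 150 of 324). Over the whole eCLIP 2 list 46.7% of clusters were eCLIP-only shared. These genes lay near that share, so the ranking goes with the number of clusters called. The gene on chromosome 4 at 20254906 to 20621866 was shorter and denser, with 129 clusters, or 3.52 per 10 kb against 1.43 per 10 kb for the richest gene. It was dense in other clusters too, with 713 in eCLIP 1, 325 in eCLIP 2 and 632 in input 1. Its eCLIP 1 clusters were 1.13 times its input 1 clusters, against 1.54 for the richest gene and 1.45 over the whole lists. Across all genes with a cluster in any library, read totals per gene ranked similarly in both eCLIP libraries and input 1, but not in the sparse input 2. Spearman's rho was 0.84 between eCLIP 1 and eCLIP 2, 0.80 between eCLIP 1 and input 1 and 0.74 between eCLIP 2 and input 1, against 0.13, 0.16 and 0.19 between input 2 and eCLIP 1, eCLIP 2 and input 1, across 21464 genes, which are not independent replicates.

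The third comparison took the input side. Of the 3553 input 2 clusters that touched input 1, 2559 touched neither eCLIP list, and they lay in 2143 genes, 1822 of which held only 1. The gene with the most of them was again ENSG00000229807, with 8 at other positions than its eCLIP-only clusters. It held 41 input 2 clusters, the most of any gene. Its 8 were a lower part of these than the 2559 of 4808 over the whole list, so its rank goes with its number of clusters. It was followed by ENSG00000245532 on chromosome 11, with 6 of 11 input 2 clusters. That gene is also the one at rank 8 of the eCLIP ranking (65199696 to 65199758), and it held 33 eCLIP-only shared clusters. After ENSG00000245532 came 8 genes with 5 each, of which the ranking takes 3 in the order of their IDs. The first of them, ENSG00000050767, had 40 reads over 9 clusters in eCLIP 1, 70 reads over 13 clusters in input 1, and 40 reads over 5 clusters in input 2. Another, on a span of 505.7 kb, carried 0.0850% of eCLIP 1 and 0.0698% of input 1 cluster reads and also held 44 eCLIP-only shared clusters. The most significant cluster shared by both inputs alone was at chromosome 17, 66342631 to 66342665, on the plus strand, with 126 reads in input 1 and 126 in input 2, and the next was at chromosome 5, 149246771 to 149246806, on the minus strand, with 124 and 108 reads. In the latter gene neither eCLIP list held a cluster.

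The mitochondrial genome took a smaller share of cluster reads in eCLIP than in input. It was 0.854% in eCLIP 1 and 1.35% in eCLIP 2, against 5.67% in input 1 and 17.4% in input 2 (mean 1.1% ± 0.353 against 11.5% ± 8.27, SD, n = 2 each). Both replicate pairs had this direction. With the 4808 most significant clusters of every library the shares were 6.50%, 5.08%, 22.4% and 17.4% in the same order, a smaller ratio with the same direction. The exact two-sided permutation test of the 4 libraries gave p = 0.33, the smallest this design allows, and 0.389 after Benjamini-Hochberg adjustment over the 7 measures compared this way. By depth, eCLIP 2 had fewer cluster reads than input 1 and the lower mitochondrial share.

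Clusters of eCLIP lay closer together along the RNA than random placement within their genes gave. After overlapping or adjoining clusters of a library were merged, 35.3% in eCLIP 1 and 21.8% in eCLIP 2 had a neighbour within 100 nt, which was 2.12 and 3.81 times the mean of 20 random moves within the gene. In input 1 and 2 the shares were 17.1% and 1.97%, or 1.17 and 1.12 times the moved mean. The input 1 value also exceeded all of its moves, which reached 14.8%, while the input 2 value lay within the range of its own, which reached 2.30%. Between the groups the exact permutation p was again 0.33. In lists of equal length, with the 4808 most significant clusters, the order in pair 1 turned: 26.7% in eCLIP 1, 21.2% in eCLIP 2, 27.9% in input 1 and 1.97% in input 2.

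Position along the gene also differed between the lists. In genes with a span of at least 2000 nt, 9.59% of eCLIP 1 and 9.35% of eCLIP 2 clusters lay in the last 10% of the span, at its 3′ end, against 12.5% of input 1 and 20.1% of input 2 clusters. The first 10% held 13.8% and 14.6% of the eCLIP clusters and 16.1% and 22.4% of the input clusters. Clusters in genes with a span over 100 kb made up 59.0% and 54.9% of the eCLIP lists and 49.4% and 43.2% of the input lists, whereas those in spans under 10 kb made up 3.52% and 4.25% against 6.13% and 21.7%. Each of these differences had the same direction in both pairs, with an exact permutation p of 0.33. The ends of a span are set by the clusters themselves and are not annotated gene ends. A gene with few clusters therefore has them at its span ends by construction. The median number of clusters per gene was 8 and 3 in eCLIP 1 and 2, and 7 and 1 in input 1 and 2. Part of the differences in the first and last 10% may thus be built in.

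**Figure D4:**
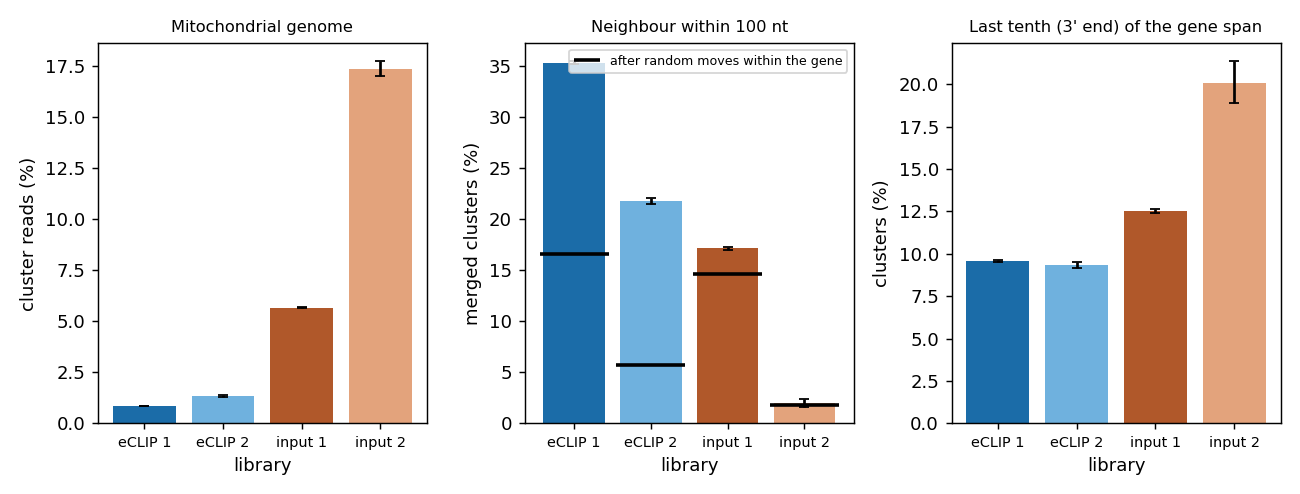
Per library (x axis): percent of cluster reads on the mitochondrial genome, percent of merged clusters with a neighbour within 100 nt (black lines: mean of 20 random moves within the gene), and percent of clusters in the last 10% of the gene span; error bars are 95% Wilson intervals for counting error. The eCLIP libraries have the lower mitochondrial shares (0.854% and 1.35%) and, for neighbours, lie above their moved means (35.3% and 21.8%) by a larger factor than input 1 (17.1%), which also lies above its own.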

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

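The overlap of eCLIP 2 with eCLIP 1 exceeded all 100 within-gene moves under each of the 7 alternatives run, from 50.3% with the N most significant clusters of each library to 98.3% at p-values below 1e-10. Its excess over the overlap with input 1, 42.9 percentage points, was 67.6 at p-values below 1e-05, 63.2 at 1e-10, 37.8 with the N most significant clusters, 41.7 with 50% of the cluster covered and 40.8 with equal lengths of the eCLIP 1 and input 1 lists. The p-value filters shortened input 1 more: 123814 eCLIP 1 and 37934 input 1 clusters were left at 1e-05, and 48846 and 11914 at 1e-10. The larger excess at these filters cannot be told apart from this difference in list length. The count of eCLIP-only shared clusters, 40044, fell to 5384 at 1e-05, 1215 at 1e-10 and 1920 with the N most significant clusters, since each list then holds fewer clusters. It stayed within 1.5 times under 6 alternatives, and was 40058 without the shallow input 2 and 40017 without the first-ranked gene. Leaving out a replicate replaces a shared count by a count in 1 pair, and gave 85209 to 474746 clusters. The replicate overlap itself cannot be computed with 1 replicate. With the replicate block, in which each eCLIP library was set only against the input of its own number, the count was 39283. The numbers are not stated to mark a shared culture, and over 2147 genes the deviations of same-numbered libraries correlated at 0.23. This value cannot decide on pairing, since both number 2 lists are the shallower of their group and every list starts at 3 reads. The mitochondrial difference, -10.4 percentage points, was -20.9 at 1e-10, while that in neighbours, 18.99 percentage points, was 9.03 with the N most significant clusters, where the order in pair 1 turned, and that in the last 10%, -6.85, ranged from -10.9 to -5.29 over other cluster or gene sets. Without a replicate, the mitochondrial difference ranged from -16.0 to -4.82, that in neighbours from 18.2 to 19.8 and that in the last 10% from -10.7 to -2.95 percentage points. The alternatives planned for gene lists, regions, motifs, stop codons, annotated 3′ ends and splice sites were not run. Depth limits what a missing overlap means: with 3 reads per cluster, 49.9% of eCLIP 2 clusters met eCLIP 1, and input 2 is too sparse to act as a filter.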

Other observations

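The number of eCLIP-only shared clusters varied along the genome. Among 3440 windows of 500 kb that held any, the median window held 7 and the fullest held 200, at chromosome X, 73000001 to 73500000. This window contains the clusters ranked 1, 6 and 18, which belong to 3 genes on both strands, and it held 1013 eCLIP 1, 492 eCLIP 2, 831 input 1 and 42 input 2 clusters. Next came windows on chromosome 16 at 78500001 to 79000000 with 129 and on chromosome 22 at 28500001 to 29000000 with 128. In these windows eCLIP 2 had 301 and 273 clusters of any kind. Across the whole eCLIP 2 list, 46.7% of clusters were eCLIP-only shared. The fullest window and those on chromosomes 16 and 22 lay near or below this share, so their counts go with the number of clusters called there. Most of the 15 fullest windows drew on 3 genes or fewer, but adjoining windows on chromosome 19, from 37000001 to 38000000, held 97 and 93 eCLIP-only shared clusters in 13 and 10 genes. They held 161 and 197 eCLIP 2 clusters of any kind, so the first of them lay above the share of the whole list.

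For the patterns that follow, the tests of overlap and of read numbers in both inputs were chosen after the results were seen, and the tests of cluster width before. The first pattern is that eCLIP 2 clusters met eCLIP 1 more often than input 1. A longer eCLIP 1 list is argued against as the whole cause, because 63.7% of eCLIP 2 clusters still met eCLIP 1, against 22.9% for input 1, when both lists had equal length. That cut kept the most significant eCLIP 1 clusters and left input 1 whole, so a small fall was likely. With every list cut to its 4808 most significant clusters, the shares were 50.3% and 12.4%. Read depth stayed unequal in both settings. Shared abundant genes with clusters placed evenly over their spans are argued against, because the highest of 100 within-gene moves reached 7.82%. The moves do not keep exons, and all 12 ordered pairs of libraries exceeded theirs, pairs of eCLIP with input included. This test therefore cannot decide on abundant exonic RNA shared by both eCLIP libraries. Places where reads of any library pile up are argued against as the whole cause, because input 1 would have met most of the shared clusters too, and it met 29.0% of them; of the eCLIP 2 clusters with 20 or more reads, however, 76.0% met input 1, so such places may add to the strongest clusters. Binding by FLAG-PTBP1 remains a hypothesis that may explain the pattern: RNA that sticks to the antibody or beads would recur in both eCLIP libraries too, and a pulldown from cells without the tag was not analysed here.

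The second pattern is the narrow clusters of input 2, with a median width of 18 nt against 30, 27 and 33 nt in eCLIP 1, eCLIP 2 and input 1. Few reads per cluster are argued against as the whole cause, since among clusters of exactly 3 reads the median was 14 nt in input 2 and 20, 21 and 26 nt in the others, a ratio of 0.70 to the lowest of these. Clusters in places that only input 2 calls are also argued against as the whole cause, since the 3553 that touched input 1 had a median of 19 nt, 0.576 of that of input 1. That ratio was not matched on reads. The 1255 that touched no input 1 cluster were narrower, with a median of 15 nt, so such places may add to the pattern. Shorter aligned fragments in this library are a possible explanation that was not tested, since read lengths were not analysed here, and no biological explanation was tested.

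The third pattern concerns the 105 input 2 clusters of at least 20 reads, each in a different gene, that touched input 1 and no eCLIP cluster: although input 1 had 67.0 times the cluster reads of input 2, the median ratio of input 2 to input 1 reads was 0.881 (quartiles 0.769 and 1.08), and it was over 0.5 in 103 of them. Reads in proportion to depth, which need a ratio near 0.0149, are argued against for these clusters, and the 169 clusters of that strength that touched input 1 and eCLIP, 21 of them mitochondrial, had a median ratio of 0.149 (quartiles 0.0515 and 0.694), over 0.5 in 66, so that similar read numbers were not confined to clusters without eCLIP contact. This holds only for clusters picked by their reads in input 2: of all input 1 clusters of at least 50 reads, those without eCLIP contact had an input 2 cluster in 14.3% of cases and those with contact in 29.9%, with median ratios of 0.050 and 0.0417 where they had one. Abundant RNA of the gene around them is argued against as the whole cause of the similar read numbers, in the 41 genes with another input 1 cluster of 10 or more reads. At equal abundance in both inputs it would follow depth, and if it were more abundant in input 2, other clusters of the gene would share this. Of the 560 such other clusters in those 41 genes, 14.3% (95% Wilson interval 11.6 to 17.4) met input 2, and 5.85% of 376 without the gene that held the most. Over all input 1 clusters, of any read number, 0.999% met input 2, so abundant RNA may add to the pattern in some genes. That share was not matched on reads. The rest of the 105 genes had no such other cluster, and for them the test cannot decide. An earlier test, the part of the gene's input 1 cluster reads held by the cluster (median 42.4%), did not bear on this explanation. A sequence carried into both inputs in similar amounts is a possible source that was not tested and would need the reads, and no biological explanation was tested.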
